A study of Rattus norvegicus with 4 samples.

How the data were processed

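Total RNA from the uterus of Sprague Dawley rats on day 5 of pregnancy was measured on 4 Affymetrix whole-transcript arrays, 1 per biological replicate. The groups, as the labels name them, were 2 replicates from rats fed ormeloxifene in gum acacia at 1.25 mg per kg on day 1 of pregnancy and 2 replicates from rats given the vehicle. Per the labels' protocols, RNA was extracted with Trizol and 100 ng was converted into biotin-labelled single-stranded DNA. Whether an array held RNA of 1 rat or of several is not given in the sources used here. The number of arrays limits the precision of every value. The p-values of single genes measure spread between the labelled biological replicates, moderated by the spread shared between genes. The 2 replicates of a group carry the numbers 1 and 2. Without a block, that spread therefore also holds any difference between the numbers.

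The deposited table holds log2 values for 36685 probe sets on each array. Per the submitters' processing notes, the authors used Affymetrix Expression Console; its version, its summary method and the genome build behind the probe sets are not given in the sources used here. The log2 scale was taken from the values, which ran from 0.92 to 13.59. The columns had not been brought to a shared distribution: their medians were 5.67 and 5.93 in the ormeloxifene arrays and 5.72 and 5.84 in the vehicle arrays. The design written before the data were examined asked for quantile normalization in that case, and it was applied over all probe sets. Signal over background was not part of the table, so a dim probe set is described by the percentile of its mean among the genes tested.

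Platform annotation gave exactly 1 gene symbol for 18511 probe sets, several for 575 and none for 17599. Of the 18511, 18394 were matched by gene number to the GRCr8 annotation, which was used for names only. For the 291 genes with several probe sets, the one with the highest mean over the 4 arrays was kept, which left 18166 genes. Differences are ormeloxifene minus vehicle on the log2 scale, from limma 3.58.1 (lmFit and eBayes, no trend, not robust, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 7.55 after moderation. The 42 gene lists, which hold 947 distinct symbols, some of them in several lists, were tested with camera in limma at a preset correlation of 0.01 and adjusted over the lists. Beside it stand camera with a correlation estimated per list, fry, and the number of members past the threshold adjusted over the list alone. Camera sets the members of a list against the other genes, so its p-values at the preset correlation rest mainly on spread between genes. With an estimated correlation it uses only the residual degrees of freedom of the fit, 2 here and 1 with the block below. A call can then be lost for that reason alone, so a loss in that setting does not tell how far members are correlated. The lists, tests and naming rule, and most of the alternatives, were fixed before the data were examined.

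The rule for named genes had 3 parts. The first took the 12 genes with the largest change in each direction among genes past the adjusted threshold with groups that did not overlap. Empty places were filled by smallest unadjusted p among genes with unadjusted p under 0.05, an absolute log2 difference of at least 1 and no overlap; genes without an established symbol were counted but not named. The second part took Esr1, Esr2, Pgr and Greb1, of which Greb1 was not analysed here. The third took the 4 members with the smallest p from each list described.

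Exactly equal deposited values at the same probe set occurred 1039 times between arrays with the same replicate number (488 and 551) and 0 times in the 4 other pairs of arrays. Arrays of a number were therefore treated as a processing batch that holds both groups, a choice made once these values had been seen; the labels name no batch. The block itself was among the alternatives fixed earlier. Differences within each number are given for the genes named by the first part of the rule and as medians for the lists described. Values with the number as a block are given for the same genes and the lists called. On simulated arrays of 18166 genes with 200 of them changed and no number effect, the fit without a block called 49 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 6 false calls. With a simulated number effect of the size estimated from the arrays, it called 5 and 99 with 0 false calls, and the block fit called 99 and 100 with 35 false calls, against 50 and 100 with 14 false calls when no number effect was simulated. In the list test on simulated data, a list shifted by -0.5 was called and 0 of the other lists were. The simulated genes varied independently of each other, whereas the estimated correlation in the cell cycle list was 0.352. The simulation therefore does not show how often camera makes false calls in lists of correlated members.

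Alternatives covered the normalization between arrays, 2 filters on dim probe sets, averaging probe sets of a gene, testing all probe sets, an intensity trend with and without robust moderation, the replicate block, a fold threshold, array weights, the set tests and leaving out each array in turn. Leaving out an array leaves 1 group with a single array, which limma then takes to vary like the arrays of the other group. Intervals of list medians come from 10000 bootstrap draws over members and cover the spread between members only. Probe sets with several symbols or none were left out of the gene comparison.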

Results

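Transcripts of the rat uterus were measured on day 5 of pregnancy, before implantation, on 2 arrays from rats fed ormeloxifene and 2 arrays from rats given the vehicle alone. Ormeloxifene is a non-steroidal selective oestrogen receptor modulator used as an oral contraceptive, and it was given once, at 1.25 mg per kg on day 1. The comparison asks which uterine transcripts differed between the groups at that time. Values are log2 signals after quantile normalization, given as mean ± SD over the 2 arrays of a group; differences are ormeloxifene minus vehicle with their standard error.

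The largest difference in the uterus was that of Oxt, which encodes the precursor of oxytocin and its carrier neurophysin. Its signal was 5.94 ± 0.24 with vehicle and 9.09 ± 0.37 with ormeloxifene, a difference of 3.16 ± 0.26 or 8.91-fold. Next among the named higher genes came RT1-Db1, a beta chain of the rat class II histocompatibility complex, at 3.89-fold higher, and Grik2, a kainate receptor subunit, at 3.26-fold higher. On the lower side stood Mbnl3, an RNA-binding protein of the muscleblind family that acts in splicing, at 3.22-fold lower, and Aadat, an aminotransferase of lysine and kynurenine metabolism, at 2.99-fold lower. The probe sets behind these 5 genes were 17766338 for Oxt, 17756758 for RT1-Db1, 17759443 for Grik2, 17879267 for Mbnl3 and 17711471 for Aadat. A list of 33 cell cycle genes lay lower with ormeloxifene, at a median of -0.47. The call by camera was lost with an estimated correlation (adjusted p = 0.792), a setting with only 2 degrees of freedom. Without vehicle replicate 2 the median was -0.18.

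By limma without a block, 0 of the 18166 genes were higher and 0 were lower at an adjusted p under 0.05. The smallest adjusted p was 0.0528, that of Oxt. At an unadjusted p under 0.05 there were 399 genes, 203 higher and 196 lower, against 908 expected by chance with exchangeable arrays. That split depended on the scaling: it was 57 higher and 85 lower on the values as deposited, and 112 higher and 183 lower with arrays centred on their medians. Leaving out vehicle replicate 1 gave 706 genes at an unadjusted p under 0.05 and leaving out vehicle replicate 2 gave 945, where 1 group is a single array taken to vary like the other group. On the same assumption the adjusted p of Oxt ran from 0.00135 without vehicle replicate 1 to 0.0561 without ormeloxifene replicate 2. Over all settings it ran from 6.05e-13 with the number as a block on the values as deposited to 1.00 with all probe sets tested. An absolute log2 difference of at least 1 was seen in 38 genes, 22 higher and 16 lower. The groups did not overlap in 25.7% of genes, where chance gives 33.3% with 2 arrays against 2 that are exchangeable. Arrays with the same replicate number resembled each other across the groups, so the arrays cannot be taken as exchangeable. A difference between the numbers makes small p-values without a block, and groups that do not overlap, rarer than these figures. Values below 908 and 33.3% therefore do not show that fewer genes differed than by chance. An exact permutation test of a single gene cannot go below p = 0.333 in this design.

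The arrays were more alike by replicate number than by group. Across genes, arrays with the same number correlated at r = 0.980 and 0.983, the 2 ormeloxifene arrays at 0.973 and the 2 vehicle arrays at 0.963; genes are not independent replicates. Splitting the 4 arrays by number gave 3716 genes at an unadjusted p under 0.05 and 0 past the adjusted threshold. The remaining split, which crosses group and number, gave 266 genes at an unadjusted p under 0.05 and 26 with an absolute log2 difference of at least 1, against 399 and 38 between the treatment groups. With the number as a block, 3 genes were higher and 2 lower at an adjusted p under 0.05, and 1228 genes had an unadjusted p under 0.05. The 5 genes were Oxt (adjusted p = 0.00904), RT1-Db1 (0.0175), Grik2 (0.0339), Mbnl3 (0.0339) and Aadat (0.0384). Their differences within number 1 and within number 2 were 2.73 and 3.58 for Oxt, 1.94 and 1.98 for RT1-Db1, 1.57 and 1.83 for Grik2, -1.72 and -1.65 for Mbnl3, and -1.52 and -1.63 for Aadat. The same sign within both numbers follows from groups that do not overlap, so it adds no support. On the values as deposited the block fit called 40 genes higher and 44 lower, all 5 among them. The block fit leaves 1 residual degree of freedom per gene. After moderation it had 8.15, and on the values as deposited 39.5, so the p-values of the latter rest almost wholly on the variance shared between genes. That fit therefore called genes mainly by the size of their difference, Hapln2 at -0.83 among them. On simulated arrays with 200 genes changed, the block fit on normalized values made 35 false calls with a number effect and 14 without one. Beside the 35 it called 99 of 100 genes changed by 1 and 100 of 100 changed by 2. Those counts therefore do not give the number of false calls to expect among 5. The fit on deposited values was not simulated.

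The other 9 genes that filled the list of 12 higher with ormeloxifene did not pass the adjusted threshold by limma without a block, nor with the number as a block (adjusted p from 0.0627 to 0.228). All 9 passed with the block on the values as deposited, from 3.14e-06 for Aqp8 to 0.00293 for Or2y1c. That fit called genes mainly by size, and these were chosen for an absolute log2 difference of at least 1. Their passing therefore adds no support. Their differences ran from 0.97 to 1.97 within number 1 and from 0.83 to 1.44 within number 2. Aqp8, a water channel, was 5.48 ± 0.36 with vehicle and 7.13 ± 0.10 with ormeloxifene, a difference of 1.65 ± 0.24. Lrrc26, an auxiliary subunit of large-conductance potassium channels, differed by 1.35 ± 0.21. The peptidylarginine deiminase Padi2 differed by 1.25 ± 0.21, from a vehicle signal of 7.61 ± 0.15. For complement component C3 the difference was 1.18 ± 0.21, and for the endonuclease Dnase1 it was 1.20 ± 0.23. RT1-CE16, a class I histocompatibility gene, differed by 1.41 ± 0.26 and Layn, a membrane receptor for hyaluronan, by 1.12 ± 0.22. Ly6i (1.29 ± 0.22) and the olfactory receptor Or2y1c (1.21 ± 0.25) were dim, at the 9.87th and 3.14th percentile of signal.

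On the lower side, Prokr2, a receptor for prokineticins, was 7.50 ± 0.07 with vehicle and 5.94 ± 0.21 with ormeloxifene, a difference of -1.55 ± 0.22. Alb, which encodes albumin, differed by -1.34 ± 0.21 from a vehicle signal of 8.55 ± 0.08. The difference was -1.55 ± 0.25 for Nexmif and -1.27 ± 0.23 for Cited1, a transcriptional coregulator. Mup5, of the major urinary protein family whose members share much of their sequence, differed by -1.39 ± 0.31. The remaining 5 of the 12 were dim, between the 1.06th and the 13.2th percentile: Vom2r78 (-1.07 ± 0.21), Khdc1b (-1.16 ± 0.23), Mir30c1 (-1.06 ± 0.22), Ppp4r3cl2 (-1.21 ± 0.26) and Or14a257b (-1.07 ± 0.24). These 10 genes did not pass the adjusted threshold by limma without a block, nor with the number as a block (adjusted p from 0.0627 to 0.255). All 10 passed with the block on the values as deposited, from 1.05e-05 for Prokr2 to 0.00539 for Or14a257b. As with the higher genes, this follows largely from their choice by size and adds no support. Their differences ran from -0.92 to -1.65 within number 1 and from -0.76 to -1.86 within number 2.

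**Figure D1:**
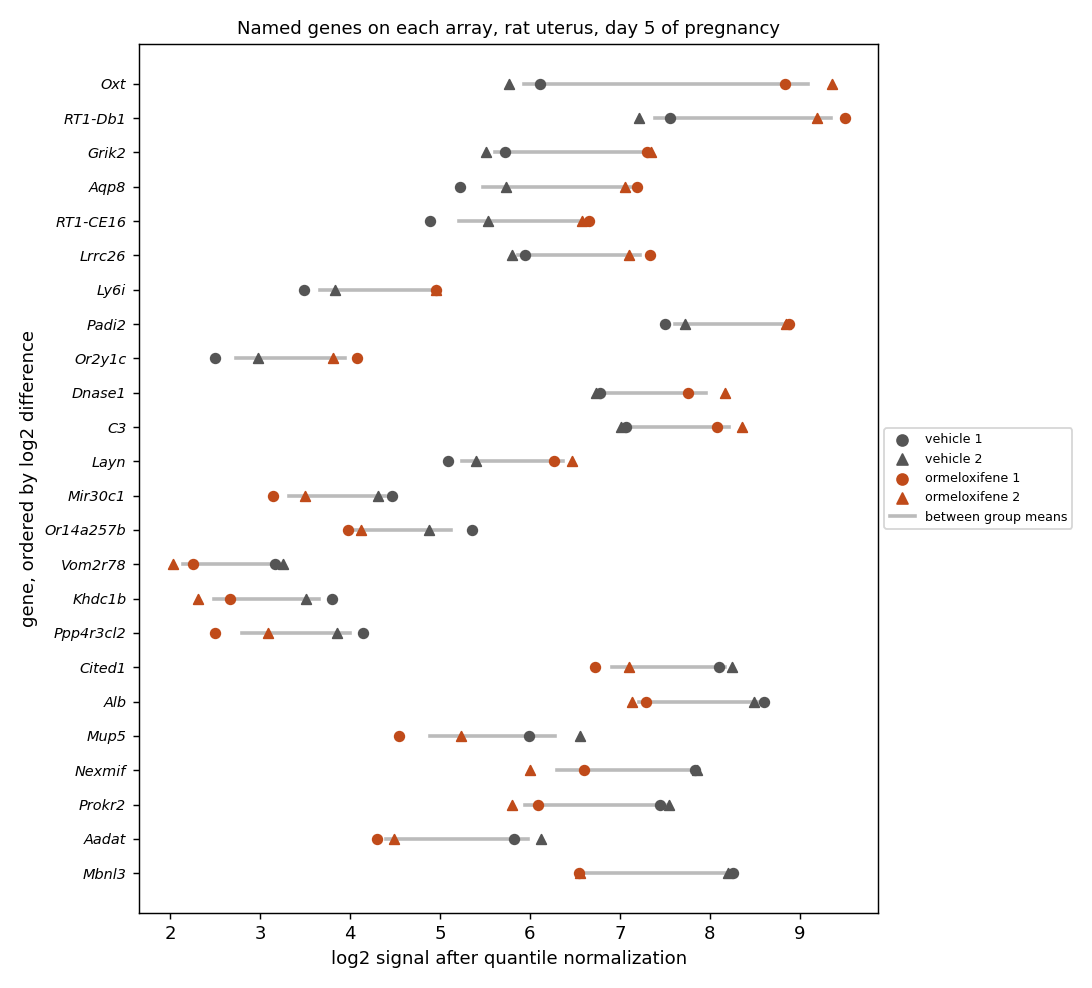
Signal of the 24 named genes on each array, on a log2 axis after quantile normalization, with 1 row per gene; grey symbols are vehicle arrays, orange symbols ormeloxifene arrays, circles replicate 1 and triangles replicate 2, and the bar joins the group means. The symbols of the groups do not overlap in any row, which the choice of genes required, and the widest gap is that of Oxt at 3.16.

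The receptors through which oestrogen and progesterone act showed no detectable difference. Esr1, the main oestrogen receptor of the uterus, was 9.54 ± 0.34 with vehicle and 9.34 ± 0.03 with ormeloxifene, a difference of -0.20 ± 0.24 with a 95% interval from -0.75 to 0.35. For Esr2 the difference was -0.02 ± 0.22 (-0.52 to 0.49), and for the progesterone receptor Pgr it was -0.25 ± 0.22 (-0.77 to 0.27). Within number 1 and number 2, Esr1 differed by 0.06 and -0.46, Esr2 by -0.12 and 0.08, and Pgr by -0.06 and -0.44. Esr1 differed by -0.44 without vehicle replicate 1 and by 0.04 without vehicle replicate 2, and Pgr by -0.45 without ormeloxifene replicate 1 and by -0.06 without ormeloxifene replicate 2. Over the list of 19 steroid receptors and coregulators, 11 members were higher and 8 lower, 0 at an unadjusted p under 0.05, with medians of 0.15 within number 1 and -0.06 within number 2. The members of smallest p were the coactivators Ncoa3 (0.30 ± 0.20) and Ncoa2 (0.30 ± 0.22), the latter 0.15 without vehicle replicate 1. The glucocorticoid receptor Nr3c1 (0.28 ± 0.25) was 0.01 without vehicle replicate 1 and 0.55 without vehicle replicate 2.

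Genes known to be induced by oestrogen in the uterus went both ways, 13 higher and 14 lower of 27 measured. Adjusted over the list alone, 2 members passed, Padi2 and C3, both higher and the smallest at 0.00932; over all genes tested, 0 did. Sfrp4, a secreted Wnt antagonist, differed by 0.90 ± 0.24 and the calcium-binding S100g by 0.90 ± 0.33, whereas Gadd45g, a stress-response gene, differed by -0.74 ± 0.23 and the water channel Aqp5 by -0.68 ± 0.27. Without ormeloxifene replicate 1, S100g was 1.31 and Aqp5 -1.03, and without ormeloxifene replicate 2 they were 0.49 and -0.34; without vehicle replicate 1, S100g was 0.61. With the block on the values as deposited, Padi2 (0.000341), C3 (0.000856), S100g (0.0255) and Sfrp4 (0.0337) passed the adjusted threshold over all genes. The list as a whole was not shifted by camera (adjusted p = 0.929); its median was -0.02, its mean 0.06 and the direction of the test was up. Within number 1 and number 2 the median was -0.02 and -0.08. By fry's test of change in either direction the list had an adjusted p of 0.0222, and 0.149 with the number as a block.

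Progesterone-induced genes, receptivity factors and decidualisation genes were not shifted as lists, with adjusted p of 0.912, 0.731 and 0.942 by camera. Of the 24 progesterone-induced genes measured, 13 were higher and 11 lower. Examples are the transcription factor Zbtb16 (0.53 ± 0.21), the calcitonin gene Calca (-0.50 ± 0.21) and the activin antagonist Fst (0.42 ± 0.21). Il13ra2, the decoy receptor of interleukin 13, was 0.45 ± 0.20 at its brightest probe set and -0.17 with its 2 probe sets averaged. Of 32 receptivity factors, 14 were higher and 18 lower, with the cannabinoid receptor Cnr1 at -0.58 ± 0.22, Stat3 at -0.45 ± 0.21 and the homeobox gene Msx2 at 0.40 ± 0.20. Of 25 decidualisation genes, 12 were higher and 13 lower. The insulin-like growth factor binding protein Igfbp1 differed by -1.05 ± 0.29, from -0.54 in number 1 to -1.56 in number 2 and -0.67 without vehicle replicate 2; it passed the adjusted threshold with the block on the values as deposited (0.0118). By contrast, the prolactin family members Prl8a2 (0.61 ± 0.21) and Prl3c1 (0.56 ± 0.22) were dim. The direction of the test was down for the decidualisation list, whose median was -0.04 and mean 0.00. The medians within number 1 and number 2 were 0.09 and -0.02 for progesterone-induced genes, -0.01 and 0.00 for receptivity factors and 0.01 and -0.04 for decidualisation genes. Adjusted over each of these 3 lists alone, 0 members passed.

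Cell cycle genes formed the most marked group, with 31 of 33 members lower with ormeloxifene and 2 higher. At an unadjusted p under 0.05 stood 9 members, all lower, of which 0 passed over all genes tested and 0 adjusted over the list alone by limma without a block. With the block on the values as deposited, Kif20a (0.0383), Top2a (0.0479) and Ccna2 (0.0482) passed over all genes. The mitotic kinesin Kif20a differed by -0.86 ± 0.22, the mitotic kinase Cdk1 by -0.80 ± 0.21, the cyclin Ccna2 by -0.85 ± 0.24 and the DNA topoisomerase Top2a by -0.83 ± 0.26. The list was lower by camera with the preset correlation (adjusted p = 3.13e-17, and 3.50e-17 with the number as a block). The call was lost with an estimated correlation of 0.352 (adjusted p = 0.792). That setting had 2 degrees of freedom, so the loss cannot be laid to correlation between members alone. Within number 1 the median was -0.24, with 23 of 33 members lower, and within number 2 it was -0.65, with 32 lower. The 2 vehicle arrays differed in the same list by a median of 0.46, about as much as the groups did, and without vehicle replicate 2 the median difference was -0.18 (adjusted p = 0.00792).

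**Figure D2:**
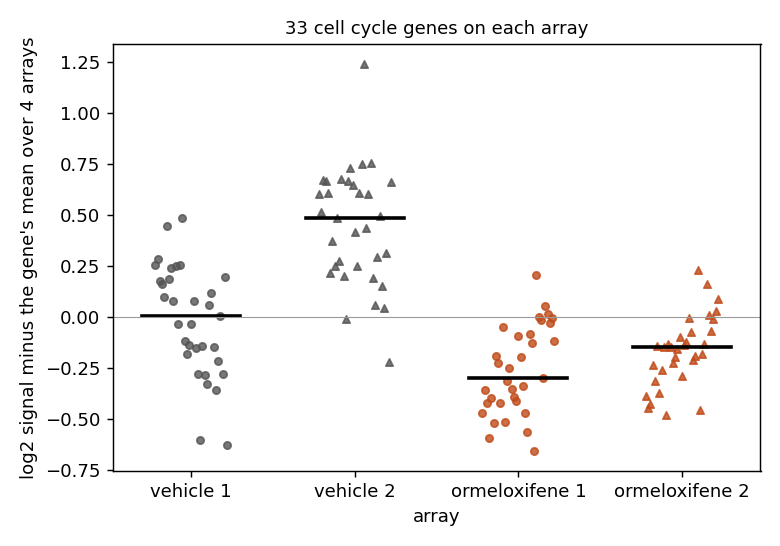
Signal of 33 cell cycle genes on each of the 4 arrays, as the log2 signal minus the mean of the same gene over the arrays; each symbol is 1 gene and the black bar the median. The median was 0.01 in vehicle 1 and 0.48 in vehicle 2, against -0.30 in ormeloxifene 1 and -0.14 in ormeloxifene 2.

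Genes of the unfolded protein response and immediate-early genes were also lower as lists by camera with the preset correlation (adjusted p = 0.00643 and 0.0119; with the number as a block 0.0110 and 0.0245). Both calls were lost with an estimated correlation (adjusted p = 0.792 each), at 2 degrees of freedom. Immediate-early genes had an estimated correlation of 0.0231, near the preset 0.01, yet their unadjusted p by camera went from 0.00113 to 0.0983. In the first list 17 of 24 members were lower, at a median of -0.13, with the asparagine synthetase Asns at -0.74 ± 0.20, Manf at -0.38 ± 0.20 and the protein disulphide isomerase Pdia4 at -0.34 ± 0.22. In the second, 17 of 21 were lower, at a median of -0.14, with the nuclear receptors Nr4a1 (-0.89 ± 0.24) and Nr4a3 (-0.52 ± 0.22) and the transcription factor Junb (-0.56 ± 0.21). Within number 1 and number 2 the medians were -0.05 and -0.20 for the unfolded protein response and -0.00 and -0.26 for immediate-early genes. From replicate 1 to replicate 2 of a group, unfolded protein response genes differed by a median of 0.24 with vehicle and -0.09 with ormeloxifene. Immediate-early genes differed by 0.03 with vehicle and -0.18 with ormeloxifene. Adjusted over either list alone, 0 members passed; with the block on the values as deposited, Nr4a1 passed over all genes (0.0413). Pdia4 was -0.18 without vehicle replicate 2. The first was lost without ormeloxifene replicate 1 (0.0703), ormeloxifene replicate 2 (0.133) or vehicle replicate 2 (0.617), the second without ormeloxifene replicate 2 (0.357), vehicle replicate 1 (0.0921) or vehicle replicate 2 (0.260), and both with all probe sets tested (0.0621 and 0.0894).

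Smooth muscle markers were higher with ormeloxifene in 17 of 17 members, at a median of 0.19 (camera with the preset correlation, adjusted p = 0.00268, and 0.00202 with the number as a block). The call was lost with an estimated correlation of 0.197 (adjusted p = 0.792), again at 2 degrees of freedom. Examples are the contractile proteins Myh11 (0.37 ± 0.22), Tagln (0.34 ± 0.22) and Synpo2 (0.45 ± 0.22). Myh11 was 0.20 without vehicle replicate 2, and without ormeloxifene replicate 1 Tagln was 0.19 and Synpo2 0.27. The medians within number 1 and number 2 were 0.22 and 0.24. From replicate 1 to replicate 2 of a group, the markers differed by a median of -0.18 with vehicle and -0.26 with ormeloxifene. At an unadjusted p under 0.05 stood 0 members. The call was also lost without ormeloxifene replicate 1 (0.227) and without vehicle replicate 2 (0.542). The other markers of the main uterine cell types were not shifted by camera: stroma markers had a median of 0.12 (adjusted p = 0.273), with the endopeptidase Mme at 0.59 ± 0.21 and Cd34 at 0.59 ± 0.24 (0.36 without ormeloxifene replicate 1), and epithelium markers a median of 0.05 and a mean of 0.01 with a test direction of down (adjusted p = 0.942), with the transcription factors Ehf at 0.66 ± 0.22 and Elf3 at -0.48 ± 0.21. The medians within number 1 and number 2 were 0.17 and 0.00 for stroma and 0.08 and -0.03 for epithelium. Markers of macrophages and dendritic cells were higher in 17 of 20 members, at a median of 0.13 (adjusted p = 0.0888; 0.11 and 0.16 within number 1 and number 2). Their leading member was the class II gene RT1-Ba, at 0.82 ± 0.22, followed by the invariant chain Cd74 at 0.38 ± 0.21.

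Of 21 complement genes, 15 were higher and 6 lower, at a median of 0.10 (camera, adjusted p = 0.0941), and 0.17 and 0.06 within number 1 and number 2. C3 passed adjusted over the list alone (0.0145) and not over all genes; the factor B gene Cfb was at 0.50 ± 0.22. With the number as a block, fry in 1 direction gave the complement list an adjusted p of 0.0285, against 0.0866 without it; camera with an estimated correlation gave 0.792, or 0.970 with the block, and fry in either direction with the block 0.149. Granulocyte and mast cell markers, 10 higher and 11 lower of 21, had an adjusted p of 0.0290 by the same fry test with the block in 1 direction, 0.932 without it, 0.521 in either direction with it, 0.464 by camera, and 0.902 by camera with an estimated correlation or 0.970 with the block as well. Its medians within number 1 and number 2 were -0.04 and -0.11. The members of smallest p were the calcium-binding S100a9 at -0.57 ± 0.23, which was -0.36 without vehicle replicate 2, and the myeloperoxidase Mpo at 0.66 ± 0.37, which was 1.42 within number 1 and -0.11 within number 2; without vehicle replicate 1 Mpo was 0.10 and without vehicle replicate 2 it was 1.22. Ion and water transport genes went both ways, 16 higher and 14 lower of 30, with medians of -0.01 and -0.03 within number 1 and number 2 (camera, adjusted p = 0.942). Aqp8 passed adjusted over that list alone (0.00541), and the sodium pump subunit Atp1b1 was at 0.61 ± 0.20.

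In the Wnt pathway list, 22 members were higher and 15 lower, and the members of smallest p were the antagonists Sfrp4 and Sfrp2 (0.61 ± 0.20), followed by the agonist Rspo3 (0.48 ± 0.21). Of 25 members of the EGF and IGF families, 16 were higher and 9 lower, with Igfbp5 at 0.62 ± 0.21 opposite to Igfbp1; the median was 0.05, the mean -0.02 and the direction of the test down. Of 22 retinoid genes, 11 were higher and 11 lower; the retinal dehydrogenase Aldh1a1 was at -0.76 ± 0.20, at a dim signal of 5.03 ± 0.03 with vehicle, and the retinol acyltransferase Lrat at -0.72 ± 0.23. In the prostaglandin pathway, 11 members were higher and 10 lower, with the phospholipase Pla2g2a at -0.73 ± 0.22, the receptor Ptger2 at -0.53 ± 0.21 and the receptor Ptgfr at 0.60 ± 0.21; its median was 0.10, its mean -0.01 and the direction of the test was down. These 4 lists had adjusted p of 0.551, 0.912, 0.433 and 0.912 by camera, in that order, and 0 members passed adjusted over the list alone. Their medians within number 1 and number 2 were 0.11 and -0.10 for Wnt, 0.09 and -0.08 for EGF and IGF, 0.02 and -0.08 for retinoid, and 0.15 and -0.04 for prostaglandin genes.

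Circadian clock genes were split, 7 higher and 8 lower of 15. Nfil3 (-0.81 ± 0.21) was lower, and Dbp (0.55 ± 0.23) and Per3 (0.53 ± 0.21) higher, none past the adjusted threshold. Bmal1 was at -0.56 ± 0.28 with an unadjusted p of 0.0772 by limma; it was -0.92 without ormeloxifene replicate 1 and -0.21 without ormeloxifene replicate 2. The median of the list was 0.08 within number 1 and -0.15 within number 2. By fry the list had an adjusted p of 0.0222 for change in either direction, and 0.149 with the number as a block; by camera it was not shifted to either side (0.912).

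**Figure D3:**
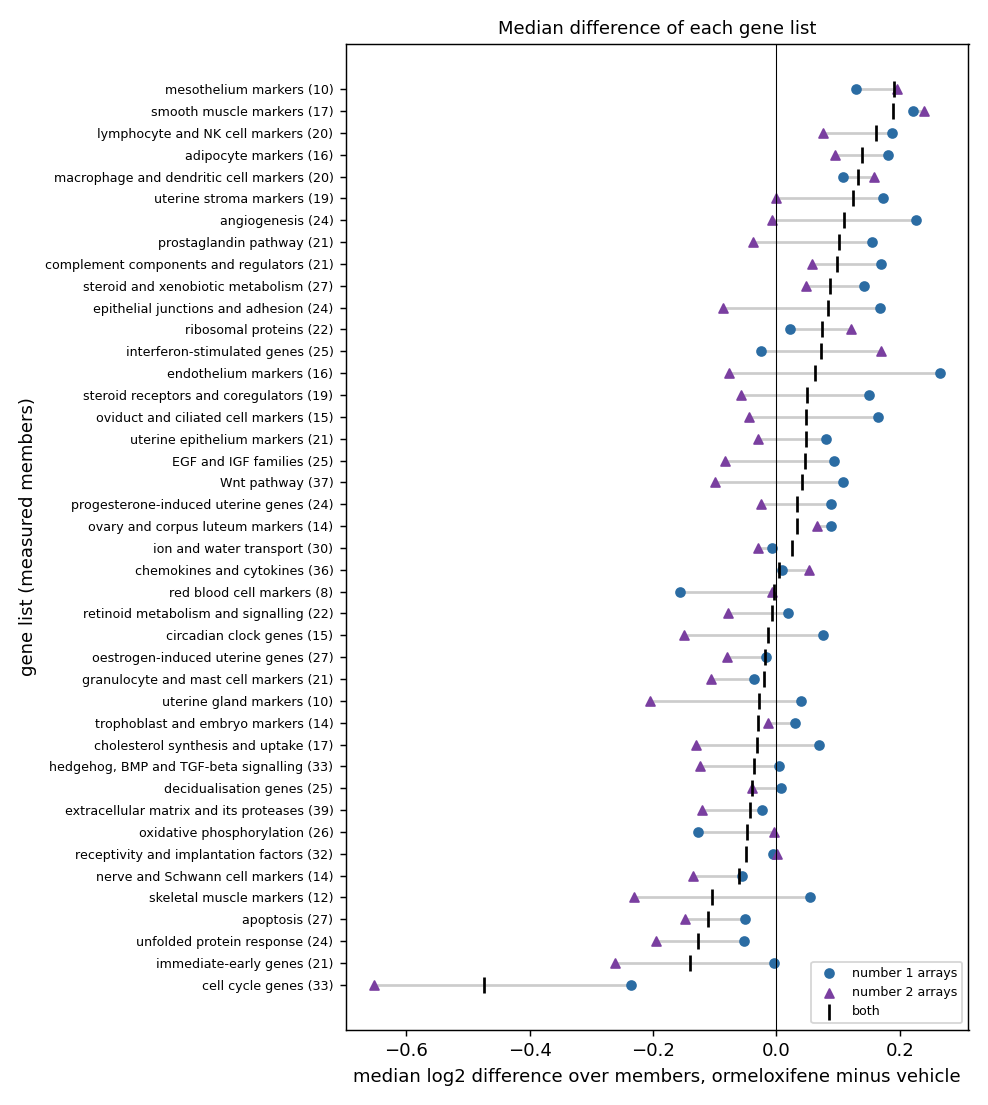
Median log2 difference over the measured members of each of the 42 gene lists, ormeloxifene minus vehicle, within the number 1 arrays (circles), within the number 2 arrays (triangles) and from both (bars). Cell cycle genes lie farthest from 0, at -0.47, and the medians of the other lists lie between -0.14 and 0.19.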

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

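The test of all probe sets was fixed in advance, and the choice to give these probe sets was made after their values were seen. Of the 17599 probe sets without a gene symbol, which the comparison between genes left out, 241 had an unadjusted p under 0.05 by limma, an absolute log2 difference of at least 1 and groups that did not overlap. Of these, 94 were higher with ormeloxifene and 147 lower. By limma 0 passed the adjusted threshold, and 664 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance gives with exchangeable arrays. The 241 are not all separate measurements, since some had identical values, such as probe sets 17607515 and 17608933. The 2 of smallest p were both lower with ormeloxifene. Probe set 17832374 differed by -2.53, down to an ormeloxifene signal of 1.34 near the bottom of the range, and probe set 17715822 by -1.76, from a vehicle signal of 8.10. What they measure is not given in the sources used here, and no biological explanation was tested.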

How the results depend on the processing

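The alternatives whose results follow were fixed before the values were seen, except the other 3 scalings, the block on deposited values, the block in the estimated-correlation and fry tests, and the removal of shared list members, which were chosen after. Against 0 genes higher and 0 lower by limma and 399 at an unadjusted p under 0.05, centring arrays on their medians gave 1 higher, leaving out probe sets under the median level 5 higher and 4 lower, and a milder filter on dim probe sets 3 higher and 1 lower. Averaging the probe sets of a gene gave 1 higher, array weights 1 higher, an intensity trend 2 higher and 1 lower, and the trend with robust moderation 3 higher and 1 lower. The replicate block gave 3 higher, 2 lower and 1228 at an unadjusted p under 0.05, and on deposited values 40, 44 and 1163. The deposited values without a block gave 142 genes at an unadjusted p under 0.05, and testing all probe sets 888. Leaving out 1 array gave from 0 higher (without ormeloxifene replicate 2) to 2 (without vehicle replicate 1), from 0 lower (without ormeloxifene replicate 1) to 1 (without vehicle replicate 1), and from 309 genes at an unadjusted p under 0.05 (without ormeloxifene replicate 2) to 945 (without vehicle replicate 2). Oxt had the smallest p in each of these fits. Why the counts moved was not tested. Against 4 lists shifted, leaving out probe sets under the median level gave 6, the milder filter 5 and an intensity trend 6, while testing all probe sets gave 2, an estimated correlation 0, fry in 1 direction 0, fry in either direction 2, fry with the block 2 in 1 direction and 0 in either, and an estimated correlation with the block 0. The lists called by fry were none of the 4: oestrogen-induced and circadian clock genes in either direction, and with the block complement and granulocyte and mast cell genes in 1 direction. Leaving out 1 array gave from 1 list (without vehicle replicate 2) to 3 (without ormeloxifene replicate 1, of which 2 were among the 4, cell cycle and immediate-early genes), and the cause was not tested. Each of the 4 lists kept its direction in every camera setting tabulated for it. Cell cycle genes kept their call in these except with an estimated correlation (0.792), and lost it by fry in 1 direction (0.783, and 0.824 with the block). Camera takes no robust setting, so none was run for lists. Without members shared between called lists, the adjusted p was 0.0146 for the unfolded protein response and 0.0276 for immediate-early genes. Of 1897 alternative values of 130 genes, 21 had the opposite sign, in 10 genes. Esr2 was 0.011 on deposited values, with and without the block, and ran from -0.17 without vehicle replicate 2 to 0.13 without vehicle replicate 1. Oxtr was 0.0023 on deposited values, with and without the block. Il13ra2 was -0.17 with probe sets averaged. RT1-Da was -0.033 with quantile normalization over the tested genes. Leaving out 1 array moved Esr1 from -0.44 (without vehicle replicate 1) to 0.039 (vehicle replicate 2), Hbb-b1 from -0.80 (ormeloxifene replicate 2) to 0.059 (ormeloxifene replicate 1) and Hemgn from -0.24 (vehicle replicate 1) to 0.041 (vehicle replicate 2). The same ranges were -0.11 (vehicle replicate 2) to 0.21 (vehicle replicate 1) for RT1-Da, -0.018 (vehicle replicate 2) to 0.33 (vehicle replicate 1) for RT1-DMa and -0.19 (ormeloxifene replicate 1) to 0.12 (ormeloxifene replicate 2) for RT1-DMb. They were -0.067 (ormeloxifene replicate 2) to 0.13 (ormeloxifene replicate 1) for Ciita and -0.062 (ormeloxifene replicate 2) to 0.026 (ormeloxifene replicate 1) for Oxtr.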

Other observations

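The tests of explanations below, and the genes RT1-Bb, RT1-CE15, RT1-Da, RT1-DMa, RT1-DMb, Ciita, Avp and Oxtr, were chosen after their values were seen, as were the 6 further lists described here out of all 42.

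Further gene groups were measured in the same comparison, and none of the lists in this paragraph was shifted by camera. Among 36 chemokines and cytokines, 18 were higher and 18 lower; the monocyte attractant Ccl2 differed by -0.76 ± 0.24 and Cxcl12 by 0.56 ± 0.24 (0.34 without vehicle replicate 2). Of 39 extracellular matrix genes and proteases, 18 were higher and 21 lower, with the aggrecanase Adamts4 at -0.70 ± 0.22 and the fibrillin Fbn1 at -0.56 ± 0.20. In cholesterol synthesis, where 6 members were higher and 11 lower, Hsd17b7 stood at 0.94 ± 0.27 and Sqle at -0.56 ± 0.20; Hsd17b7 was 0.59 without ormeloxifene replicate 1 and passed the adjusted threshold with the block on the values as deposited (0.0173). Of 27 genes of steroid and xenobiotic metabolism, 18 were higher, among them Ephx1 (0.69 ± 0.21) and the sulphotransferase Sult1a1 (0.60 ± 0.23). Interferon-stimulated genes were higher in 16 of 25, with Oas2 at 0.52 ± 0.21 and Mx2 at 0.51 ± 0.21. The haemoglobin gene Hba-a1 differed by -0.73 ± 0.21 in a list of 8 red blood cell markers with 4 members on each side. The adjusted p of these lists, in the same order, were 0.912, 0.273, 0.551, 0.273, 0.273 and 0.464, and 0 members passed adjusted over the list alone. Their medians within number 1 and number 2, in the same order, were 0.01 and 0.05, -0.02 and -0.12, 0.07 and -0.13, 0.14 and 0.05, -0.02 and 0.17, and -0.16 and -0.01.

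Beside the 8.91-fold difference of Oxt, the oxytocin receptor gene Oxtr differed by -0.02 ± 0.20 and Avp, which encodes the related hormone vasopressin, by 0.12 ± 0.21. The 95% intervals ran from -0.49 to 0.46 and from -0.37 to 0.60. Avp was 0.21 without vehicle replicate 1, 0.18 without ormeloxifene replicate 1, 0.05 without ormeloxifene replicate 2 and 0.02 without vehicle replicate 2.

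The histocompatibility genes did not move together. RT1-Db1 differed by 1.96 with a 95% interval from 1.42 to 2.51, RT1-Bb by 0.94 ± 0.20 and RT1-CE15 by 1.19 ± 0.37, whereas RT1-Da, the alpha chain that pairs with RT1-Db1, differed by 0.05 ± 0.22. RT1-CE15 was 0.79 without ormeloxifene replicate 1 and 0.72 without vehicle replicate 2; with the block on the values as deposited it passed the adjusted threshold (0.000485), as did RT1-Bb (0.0162). A larger share of antigen-presenting cells would raise RT1-Da, RT1-DMa, RT1-DMb, Cd74 and Ciita alike, yet the highest upper 95% limit among these 5, picked after their values were seen, was 0.86, that of Cd74, below the lower limit of RT1-Db1. With RT1-Ba (upper limit 1.35) and RT1-Bb (1.41) added the gap nearly closes, so a larger share is argued against only as the whole cause of the RT1-Db1 difference and stays open for RT1-Ba and RT1-Bb. Of 39 RT1 genes, 5 had an unadjusted p under 0.05 by limma, all higher. The family was picked because RT1-Db1 and RT1-CE16, which are among these 5, were named by the first part of the naming rule. The count therefore does not decide between explanations. Allele differences between rats of an outbred stock at these polymorphic genes, probe sets shared between near-identical RT1 genes, and regulation by the treatment cannot be told apart, since no genotypes were used.

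For the lower cell cycle genes, the median that lay nearest 0 among the other 3 ways of scaling was -0.47. The choice among these scalings therefore does not make the shift. All of them start from the same deposited values, so the authors' own summary and normalization could not be tested and stay open. A lower share of stroma is argued against as the whole cause. The stroma markers had a median of 0.12 (95% interval over members from -0.01 to 0.17). That lies above -0.47, and above the -0.18 without vehicle replicate 2, by more than the 0.13 between arrays of a group. For epithelium the test is left undecided, because the cell cycle shift depends on vehicle replicate 2 and the markers were not examined without it. The epithelium markers had a median of 0.048 (-0.20 to 0.19), above -0.47 by more than the 0.37 between arrays of a group. The same median lies above -0.18 by less than 0.37, and its interval reaches below -0.18. No conclusion is drawn from that, since the -0.18 leaves out vehicle replicate 2 and the marker median does not. Both intervals cover the spread between members only. As a part of the cause, tissue composition stays open and was not tested. From vehicle 1 to vehicle 2 cell cycle genes differed by 0.46, epithelium markers by 0.37, epithelial junction genes by 0.38, gland markers by 0.30 and smooth muscle markers by -0.18. Between the ormeloxifene arrays cell cycle genes differed by 0.06, epithelium markers by 0.26 and smooth muscle markers by -0.26. Between the groups smooth muscle markers were higher with ormeloxifene, at a median of 0.19. Whether 1 array makes the shift stays open, because the median without vehicle replicate 2 was -0.18 and the vehicle arrays differed from each other by 0.46. An effect of ormeloxifene on proliferation was not tested, since no count of dividing cells is among the data, and stays open.

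Arrays with the same replicate number resembled each other across both groups. The 1039 equal values between them, against 0 in the other pairs, are consistent with arrays of a number having been summarised or normalized together, apart from the other number. A difference in overall scale is argued against, since the deviations from the group means still correlated at 0.475 across genes after quantile normalization (95% interval from 0.464 to 0.487). That interval is over genes, which are not independent replicates, and does not cover spread between arrays. Arrays prepared on the same day or from related animals stay open, and no biological explanation was tested because the labels do not say what the number stands for.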
